A study of Pseudotsuga menziesii with 72 samples.

How the data were processed

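Needles of 6 Douglas-fir trees were sampled every 4 h over 2 days, and polyA RNA of each sample was sequenced as a strand-specific library on an Illumina HiSeq sequencer, with 6 libraries per pool. Each of the 72 libraries was assigned to its tree and collection by its title. The titles count hours from the first collection, which the growth protocol places at 2 AM, and clock times rest on that start. For 62 of the 72 libraries a separate collection-time label disagrees with the title, and the titles were used. The trees form 3 families of 2 trees by the names in the labels, although the family tags of families 1 and 2 carry the same number.

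The counts table, as deposited, holds raw whole-number counts for 180879 transcripts, made by the authors with Bowtie2 2.2.3 and CASAVA 1.8. The reference transcriptome is not given in the sources used here. A second deposited table holds a normalized signal for 41382 transcripts, which the submitters attribute to DESeq without a version. Over 2928206 nonzero values shared with the counts table, the normalized value equalled the count divided by one size factor per library (0.4495 to 2.401), with a largest relative departure of 7.55e-09. Of its transcripts, 247 are not among those of the counts table. Neither table pairs a transcript with a gene name or a position, so the 13 gene lists drawn up before the data were examined (clock and other plant genes) could not be used, and no set test was run.

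Library totals ran from 10.3 to 55.9 M counts (median 22.8 M). No 2 libraries were identical (0 pairs), and the highest Spearman correlation between a pair across transcripts was 0.980. As a check of the pairing by tree, each library was compared with the mean of every tree's other libraries after removal of the collection means. By this measure 70 of the 72 lay nearest their own tree, and the 2 exceptions were kept under their labels.

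Transcripts were kept by edgeR's filterByExpr with the 12 collections as groups and its default minimum counts of 10 per library and 15 in all, which left 50101 transcripts with 98.2% to 99.7% of each library's counts. Trimmed-mean (TMM) factors ran from 0.748 to 1.18. Tests were quasi-likelihood F tests in edgeR 4.0.16 under R 4.3.3 (glmQLFit with trended dispersions), two-sided where a direction is given. Benjamini-Hochberg adjustment was made within each test over all 50101 transcripts, and a transcript passed at an adjusted p under 0.05.

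The 24-hour rhythm was a cosine and sine fitted with tree and day, and its size is the fitted peak-to-trough ratio. Because the labels name the 6 trees as the units sampled repeatedly, the tree entered as a replicate block. The 6 clock times, their 6 neighbouring contrasts, day, tree and the day by clock time interaction came from fits with tree, day and clock time. A 12-hour cosine and sine were added to the 24-hour pair in a further fit. A tree by rhythm interaction asked whether rhythms differed between trees, and 1 fit per tree gave single-tree rhythms from 12 libraries each. Families were tested on counts summed per tree. A tree by block interaction, with the first 4 against the last 8 collections as blocks, was added after the data were examined. Limma 3.58.1 was used on log2 CPM with a prior count of 2 for the tests on patterns in the closing section. It also gave the counts of regrouped libraries, except those of families, which came from edgeR on counts summed per tree.

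Named transcripts were fixed by a rule before the data were examined. For the 24-hour rhythm they are the 2 of largest peak-to-trough ratio with a peak from 6:00 to 18:00 and the 2 with a peak in the other 12 h, among transcripts that passed in the pooled test and in each of the 6 trees. For the days and the neighbouring clock times they are the largest rise and the largest fall, for trees and families the 2 of smallest p. A mean of at least 10 CPM was required except for trees and families.

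Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and likelihood ratio tests, no filter and a filter of 1 CPM in every library, each tree left out in turn, no replicate block, the authors' normalized values with limma, each day alone, the collection-time label, summed counts per collection, a stricter adjusted p of 0.01, a minimum ratio of 2, and 2 other family tests. Those added later were the pair of libraries nearest another tree left out or exchanged, the last 8 or the first 4 collections alone, a tree by block term, and a linear trend over the hours in place of day. Tables were read with the R package data.table, version 1.17.8, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

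The tests were tried on simulated counts with the same design, depths and 50101 transcripts. Changes were planted only in transcripts above about 1 CPM, and noise was drawn separately for each library. A simulated rhythm of 1.5-fold was recovered for 80% of 100 transcripts and one of 2-fold for 91%, while 21 of 48301 unchanged transcripts were called. The recovery does not cover rarer transcripts, and the false calls do not cover an effect of a collection shared by the trees. Few transcripts were changed, 100 per fold in a test, against 31187 that passed the rhythm test in the data. With few changes the adjustment asks for smaller p-values, so recovery and false calls do not carry over to the data. The fitted peak missed the simulated one by a median of 0.339 h. Recovery at 2-fold was 95% for the day test, 90% for trees, 89% for families, 93% for the 12-hour term, 74% for rhythms that differ between trees, 53% for a daily curve that differs between days and 5% for a rhythm in a single tree. Apart from the planted changes the simulated trees were alike. The 89% for families therefore does not give the power where trees of a family differ.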

Results

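The data are transcript counts from needles of 6 three-year-old Douglas-fir trees, named 1A, 1B, 2A, 2B, 3A and 3B after their 3 half-sib families, grown together in Corvallis and sampled in September. Every tree was sampled at 12 collections, at 2:00, 6:00, 10:00, 14:00, 18:00 and 22:00 on 2 consecutive days, which gave 72 libraries, 12 per tree, 12 per clock time and 36 per day. Libraries held 10292760 to 55909749 counts (10.3 to 55.9 M, median 22.8 M), and the 10 most abundant transcripts of a library took 8.68% to 22.5% of them. Levels are TMM-scaled counts relative to the library total (CPM, as usually defined). Transcripts bear identifiers without gene names, so none can be tied to a function or a genome position. The tree accounted for 52.9% of the variance of log2 levels, clock time for 14.5% and day for 2.84%.

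A large part of the needle transcriptome followed a daily rhythm. To ask how many transcripts cycle over the day, a 24-hour curve was fitted across all trees and both days. Of 50101 transcripts, 31187 (62.3%) had a rhythm, with a median peak-to-trough ratio of 1.75 (interquartile range 1.39 to 2.45). The ratio reached 2 in 11814 transcripts (23.6% of those tested), 4 in 2964 and 10 in 578. Rhythms were called more often among abundant transcripts, and fewer of these had a fitted ratio of at least 2. In 4 classes of increasing abundance (median 0.269, 0.794, 3.56 and 24 CPM) the rhythmic share was 48.9%, 58.2%, 69.0% and 72.9%, and the share with a ratio of at least 2 was 37.0%, 27.2%, 19.2% and 10.95%. At low counts noise may raise fitted ratios and small rhythms may not pass. The shares therefore do not show that rhythms of abundant transcripts are smaller. A test on 6 clock times that assumes no shape passed 31199 transcripts. Libraries of a tree are repeated samples of it, so these counts describe 6 trees on 2 dates. The trees also share each collection, and a fit on counts summed over the trees of a collection passed 20402 of 50101, while without a filter 58894 of 173932 passed.

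Peaks gathered in the hours before and around dawn and in the late afternoon. Of the rhythmic transcripts, 7478 peaked from 4:00 to 8:00 and 7397 from 16:00 to 20:00. Fewer peaked from 0:00 to 4:00 (4951), from 8:00 to 12:00 (4199), from 12:00 to 16:00 (3985) and from 20:00 to 24:00 (3177). The fullest single hours were 4:00 to 5:00 (2049 transcripts) and 17:00 to 18:00 (2123). Daytime peaks, from 6:00 to 18:00, made up 50.5%. The fitted peak had a median standard error of 0.795 h, and collections lay 4 h apart.

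**Figure D1:**
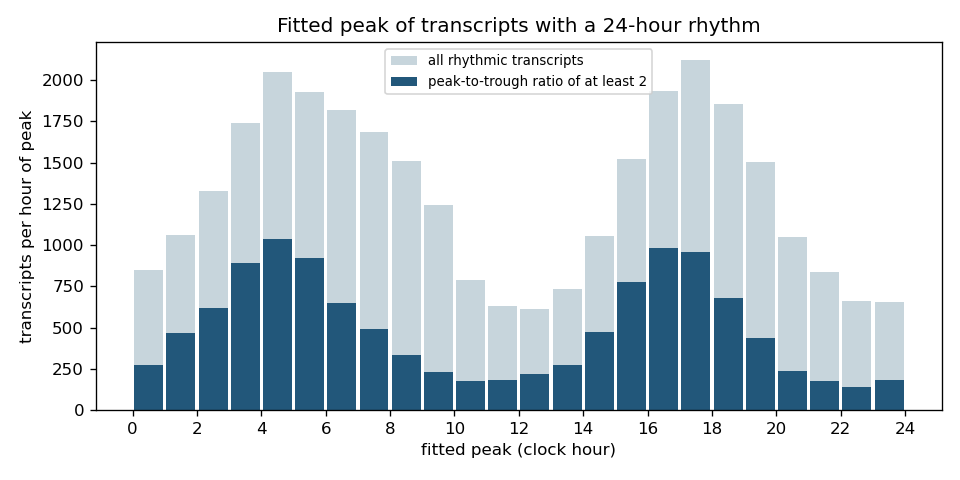
Number of transcripts (vertical axis) by fitted peak in clock hours (horizontal axis, 1 h per bar), for all 31187 rhythmic transcripts (pale) and for the 11814 with a peak-to-trough ratio of at least 2 (dark). The 2 crests lie at 4:00 to 5:00 (2049 transcripts) and 17:00 to 18:00 (2123).

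Some rhythms changed transcript levels many-fold each day. Among transcripts peaking by day, psme_t012991 stood at 37.0 ± 10.8 CPM at 6:00 and 39.3 ± 15.7 at 10:00, and at 0.183 ± 0.103 at 18:00 (SD, n = 12 libraries at each time). Its fitted log2 peak-to-trough change was 9.32 ± 0.27 (SE, adjusted p = 5.38e-40), with the peak at 7.26 h. That is a 640.8-fold ratio, more than the means at 10:00 and 18:00 span, and its 18:00 libraries held 2 to 9 counts. The SE does not cover a misfit of the cosine. For psme_t044566 the level was 614 ± 227 CPM at 14:00 and 2.96 ± 2.49 at 6:00, a fitted log2 change of 7.85 ± 0.40 (adjusted p = 3.01e-26) with the peak at 15.9 h. Among those peaking by night, psme_t005030 stood at 189.7 ± 39.4 CPM at 6:00 and 4.96 ± 1.20 at 18:00 (log2 change 5.56 ± 0.13, adjusted p = 5.48e-45, peak 5.66 h). The level of psme_t083354 was 66.2 ± 25.1 CPM at 6:00 and 1.86 ± 0.69 at 18:00 (log2 change 5.51 ± 0.20, adjusted p = 1.01e-34, peak 5.73 h). They were chosen as the 2 of largest ratio by day and the 2 by night among transcripts that passed in each of the 6 trees, and their peaks differed between trees by SDs of 0.091, 0.386, 0.162 and 0.408 h.

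**Figure D2:**
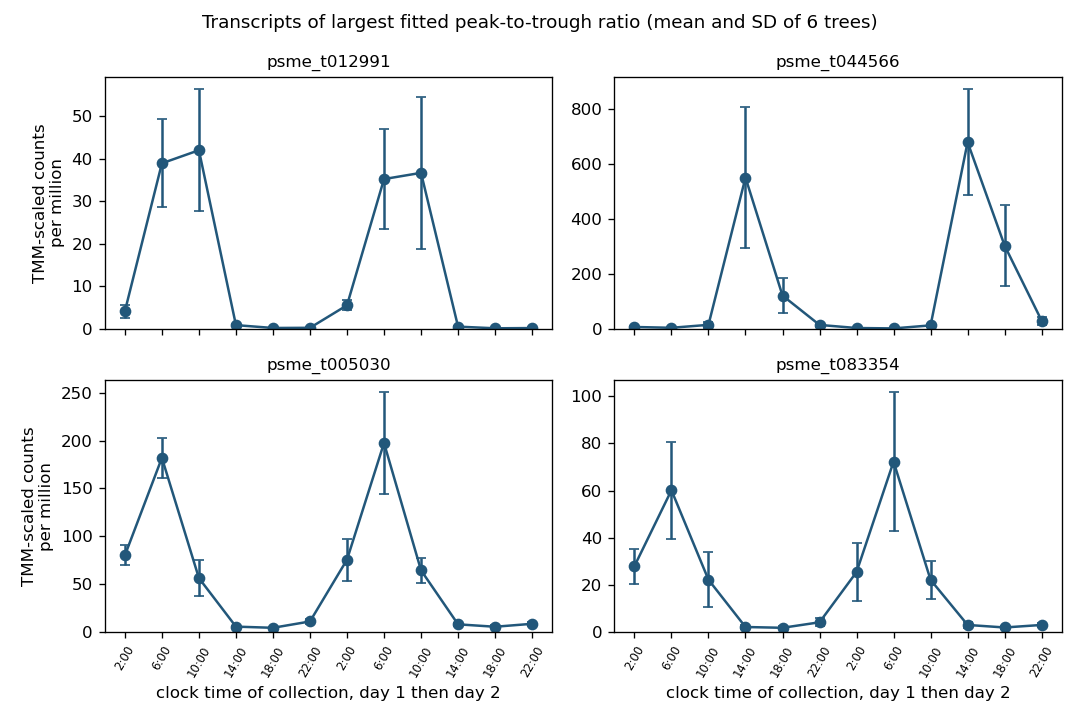
Level (vertical axis, TMM-scaled CPM) of 4 transcripts, those 2 of largest fitted ratio by day and 2 by night among transcripts that passed in each tree, at the 12 collections (horizontal axis, clock time on day 1 and then day 2), with points for the mean and bars for the SD of 6 trees. Each rises once a day at the same clock times on both days; psme_t012991 is highest at 6:00 and 10:00, psme_t044566 at 14:00, and psme_t005030 and psme_t083354 at 6:00.

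The rhythm was found again within single trees, and transcripts that passed in all 6 trees peaked at close times in them. Fitted on the 12 libraries of 1 tree, the test passed 3062 transcripts in 1A, 3810 in 1B, 3413 in 2A, 6129 in 2B, 6272 in 3A and 3517 in 3B. In all 6 trees 755 transcripts passed, with median ratios per tree of 4.81 to 5.43, and the SD of their peak between trees had a median of 0.467 h. Passing in every tree favours large and precisely timed rhythms, so this spread does not describe the other rhythmic transcripts. With 12 libraries a simulated 2-fold rhythm was recovered for 5% of transcripts, but few were changed there, which lowers recovery under the adjustment. The 5% therefore does not give the power in the data. The 38011 transcripts that passed in no single tree still cannot be read as lacking a rhythm, since failing to pass does not show absence. The count of tree 1B was 6727 with the labels of the 2 libraries nearest another tree exchanged. In the last 8 collections alone, with 8 libraries per tree, it rose to 5368 in 1B. The counts there were 217 in 1A, 2787 in 2A, 4950 in 2B, 4257 in 3A, 1527 in 3B and 143 in all 6 trees. To ask whether size or timing differ between trees, the interaction of tree and rhythm was tested, and 420 transcripts (0.838%) passed. That count was 173 without the 2 libraries whose profile lay nearest another tree.

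The most transcripts changed from 10:00 to 14:00 and the fewest at the end of the night, from 2:00 to 6:00. Between neighbouring clock times, 941 transcripts changed from 2:00 to 6:00 (594 rose, 347 fell), 9986 from 6:00 to 10:00 (4802 rose, 5184 fell) and 14228 from 10:00 to 14:00 (7153 rose, 7075 fell). From 14:00 to 18:00 the number was 7287 (3264 rose, 4023 fell), from 18:00 to 22:00 it was 8088 (4733 rose, 3355 fell), and from 22:00 to 2:00 it was 7540 (3397 rose, 4143 fell). Each step compares the clock times over both days, so that from 22:00 to 2:00 does not follow one night. All libraries of 18:00 and 22:00 lie in the last 8 collections, while the other clock times lie partly before them. The steps from 14:00 to 18:00 and from 22:00 to 2:00 therefore also carry the shift before those collections, described in the closing part. With a term for tree by block of collections, 5579 of the 7287 and 4994 of the 7540 transcripts still passed. From 10:00 to 14:00, 14204 of 14228 did, and from 18:00 to 22:00, 8081 of 8088. The count from 2:00 to 6:00 was 2041 with a term for tree by block of collections and 211 without the tree as a replicate block, in both the lowest of the 6 steps. Changes of at least 2-fold leaned to falls from 14:00 to 18:00 (470 rose, 1020 fell), to rises from 18:00 to 22:00 (2077 rose, 912 fell) and to falls from 22:00 to 2:00 (698 rose, 1413 fell). Among changes of any size the direction turned with the filter and with the collections used. Without a filter, 5222 rose and 3232 fell from 14:00 to 18:00, and 5211 rose and 6337 fell from 18:00 to 22:00. With at least 1 CPM in all libraries, 2405 rose and 2282 fell from 14:00 to 18:00, and in the last 8 collections alone 4127 rose and 4023 fell.

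**Figure D3:**
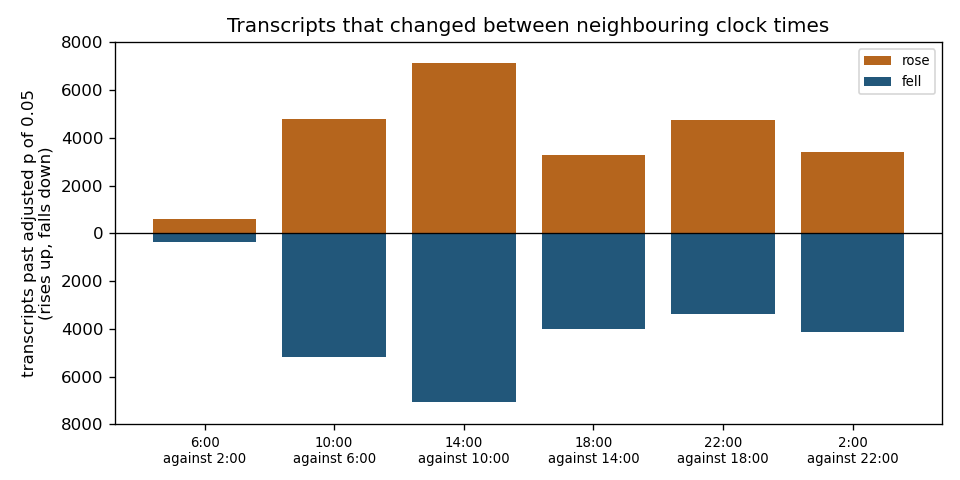
Number of transcripts past an adjusted p of 0.05 (vertical axis, rises above and falls below 0) for each step between neighbouring clock times (horizontal axis), 12 libraries per clock time. The step from 10:00 to 14:00 holds the most (7153 rose, 7075 fell) and that from 2:00 to 6:00 the fewest (594 rose, 347 fell).

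Several of the largest steps were shared by every pair of libraries from the same tree and day. The transcript psme_t012991 rose from 22:00 to 2:00 (log2 change 4.30 ± 0.25 SE, adjusted p = 1.9e-22) and again from 2:00 to 6:00 (2.93 ± 0.18, adjusted p = 1.02e-19), and it fell from 10:00 to 14:00 (−5.81 ± 0.22, adjusted p = 3.21e-32), each in 12 of 12 pairs. From 6:00 to 10:00 psme_t016053 rose from 1.35 ± 0.49 to 73.2 ± 6.9 CPM (SD, n = 12; log2 change 5.78 ± 0.18, adjusted p = 3.19e-37, 12 of 12 pairs). From 10:00 to 14:00 psme_t038959 rose from 1.70 ± 1.05 to 93.8 ± 48.0 CPM (log2 change 5.79 ± 0.26, adjusted p = 1.93e-28, 12 of 12 pairs). From 18:00 to 22:00 psme_t055959 rose (log2 change 3.20 ± 0.26, adjusted p = 1.69e-15) and psme_t044566 fell (−3.28 ± 0.32, adjusted p = 2.77e-12), and from 22:00 to 2:00 psme_t018951 fell (−3.95 ± 0.57, adjusted p = 4.11e-07), all in 12 of 12 pairs. The fall of psme_t018951 was −2.72 in the last 8 collections alone and −2.83 with the term for tree by block of collections.

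Other large steps rested on few libraries. The largest fall from 2:00 to 6:00 (log2 change −14.4 ± 2.8, adjusted p = 0.00102, 3 of 12 pairs) and the largest rise from 14:00 to 18:00 (12.4 ± 2.8, adjusted p = 0.000959, 4 of 12 pairs) were both of psme_t004418. It stood at 50320 CPM in tree 1A at hour 24 and 17360 CPM at hour 40 of the series, and no other library exceeded 7.99 CPM. Without tree 1A these changes were −0.42 and −0.29. From 6:00 to 10:00 psme_t016842 fell (−3.89 ± 0.92, adjusted p = 0.00111) in 8 of 12 pairs, and the change was −0.67 without tree 2A and −1.03 with the labels of the 2 libraries nearest another tree exchanged. From 14:00 to 18:00 psme_t055856 fell (−4.21 ± 1.16, adjusted p = 0.00798) in 7 of 12 pairs. In tree 2A psme_t055856 fell from 87.2 to 70.6 CPM on day 1 and rose from 152 to 164.2 on day 2. The remaining falls lay in other trees, the largest from 35.9 to 0 CPM in 3B on day 2. The change was −7.68 without tree 2A (adjusted p = 0.000423) and −3.46 with the 2 labels exchanged (adjusted p = 0.00118). It was −3.94, −3.92 and −2.31 without tree 2B, 3A or 3B, where it did not pass (adjusted p = 0.0505, 0.0665 and 0.231), and −0.28 without the tree as a replicate block (adjusted p = 0.98).

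The second day differed from the first in many transcripts, mostly by small amounts. To ask how far the days were alike, the 36 libraries of each were compared within tree and clock time, and 15716 transcripts (31.4%) differed, of which 6944 were higher and 8772 lower on day 2. The median size of these changes was 0.36 on the log2 scale, and 1127 reached 2-fold (720 up, 407 down). Of those that differed, 11897 (75.7%) were also rhythmic, against 62.3% of all transcripts tested, a share not matched for level or noise. Among the last 8 collections, where 18:00 and 22:00 fell on both days, 6181 differed. The lean to lower levels on day 2 turned there (3204 higher, 2977 lower), with a term for tree by block of collections (2629 higher, 2145 lower) and without the tree as a replicate block (4360 higher, 3346 lower). Each day is a single date, and a shift between the first 4 and the last 8 collections that differs between trees, described in the closing part, takes in part of the first day.

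The transcripts with the largest rise and fall between days changed in some trees and times alone. The rise was that of psme_t004418 (log2 change 4.71 ± 1.78, adjusted p = 0.0368, higher in 10 of 36 pairs), which without tree 1A was −1.20. The fall was that of psme_t148840, from 47.5 ± 61.3 to 23.7 ± 39.2 CPM (SD, n = 36; −1.83 ± 0.45, adjusted p = 0.000941, lower in 23 of 36 pairs), and in the last 8 collections alone it was −0.09. Asked whether the course of the day itself differed between days, the interaction of day and clock time passed 4158 transcripts (8.30%). The collections before the last 8 all lie on the first day, at some of its clock times alone. The shift between them and the last 8, described in the closing part, therefore lies within this interaction. The test cannot tell such a shift from a change in the course of the day. The count of 4158 also rests on the choice of libraries and fit. It was 1589 without tree 2B, 487 without the tree as a replicate block and 6341 without the 2 libraries nearest another tree. Regrouping the days could not judge it.

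Differences between individual trees exceeded those over the day. Of 50101 transcripts, 45365 (90.5%) differed between the 6 trees, and the first principal component (19.8% of the variance) followed the tree (R² of 99.1%), while the fourth (8.60%) followed clock time (R² of 76.4%). Some transcripts were nearly missing from 1 tree or found in 1 alone. The level of psme_t020329 was 0.0192 ± 0.0365 CPM in tree 2B (SD, n = 12) and 33.2 to 73.2 CPM in the other trees. The level of psme_t040613 was 31.1 ± 8.4 CPM in tree 3A and at most 0.0488 CPM elsewhere (adjusted p = 1.78e-53 for both). These tests describe the 6 trees sampled, with 12 repeated samples of each.

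Differences between families could hardly be separated from those between trees. With 2 trees per family, 11 transcripts passed a test of the 3 families (4676 at an unadjusted p under 0.05). The 2 of smallest p were found in family 3, psme_t078035 (2.92 CPM in 3A and 3.13 in 3B, at most 0.0230 in the others) and psme_t003180 (5.03 and 4.75 CPM, at most 0.120 in the others), both at an adjusted p of 0.0445. None passed when any single tree was left out (0 transcripts each time), although with fewer trees for the error the F of psme_t078035 was still 188.1 to 320, against 390.3, or when the 2 libraries nearest another tree were left out or exchanged (0). Other tests gave more, 87 with limma on mean levels per tree and 6646 with limma on libraries with an estimated correlation within trees.

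A 12-hour component was called for a minority of transcripts. A 12-hour term added to the 24-hour curve passed 8404 transcripts (16.8%), and the shapes of their daily curves were not examined. Of these, 6756 (80.4%) also had a 24-hour rhythm, against 62.3% of all transcripts tested. The count was 2942 without the tree as a replicate block and 12126 with a term for tree by block of collections. Reordered collections could not judge it.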

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

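Chosen only after the result was seen were the tests on exchanged labels, on the middle of the series, on days and clock times and on an unlabelled batch, the tree by block comparison itself, and the regrouping of libraries for all comparisons except tree by block and single trees.

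Among the 6 trees of a collection, 3 libraries stood apart. Tree 3A at hour 16 held 55.9 M counts (the other 5 trees 14.0 to 23.2 M), tree 2B at hour 36 held 41.2 M (the others 23.8 to 29.3 M), and tree 3B at hour 12 had a TMM factor of 0.802 (the others 0.971 to 1.03). In 49 such groups chance gives about 1 in 20, or 2.45.

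Groups differed in their response in 3 tests. The rhythm differed between trees for 420 transcripts and the daily curve between days for 4158. The difference between trees was itself unlike in the first 4 and the last 8 collections for 24771 transcripts. The first 4 are a part of the first day. The test of the daily curve between days therefore cannot tell a changed curve from a shift between these blocks. A further signal lies in 247 transcripts that are listed in the normalized table and not in the counts table, and that entered only the fits on normalized values.

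The libraries labelled 1B and 2A at hour 4 each resembled the other's tree. The test set the correlation of tree-specific levels, across transcripts, with the partner's tree (0.761 for the library labelled 1B and 0.746 for that labelled 2A) against those with the labelled tree (−0.24 and −0.26), where the lowest own-tree value of the other 70 libraries was 0.552. Mixed RNA is argued against, since transcripts private to the labelled tree stood at a median of 0% of that tree's level in both libraries. Those private to the partner's tree stood at a median of 96.5% of the partner's level in the library labelled 1B (15 transcripts). In the library labelled 2A the median was 84.9% (11 transcripts). Each library thus held the private transcripts of the other's tree, which goes with exchanged labels. Exchanged labels are a candidate explanation that met its test (0.746), found and tested on the same data. No biological explanation was tested, and exchanging the labels raised the rhythmic count of tree 1B from 3810 to 6727.

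Levels stepped between hours 12 and 16, in different directions in different trees, except that on the leading residual component tree 2B declined gradually (31.7, 15.1, 2.99 and −6.50 at hours 12, 16, 20 and 24) and tree 1A rose less clearly, from a mean of −19.6 ± 18.8 (SD) in the first 4 to 9.79 ± 18.2 in the last 8 collections. Without the doubted pair, 23118 transcripts had a tree by block difference in limma, and on that component (15.2% of variance) tree 3A went from a mean of 79.4 to −39.7 and tree 2A from −55.2 to 20.7. For a steady drift the test set beforehand was undecided (8405 with a line per tree), and parting the series between hours 20 and 24, tried afterwards, gave 5943, which argues against a straight drift as the whole cause but not against one that levels off or one in tree 2B. For days and clock times the first tests found 1 of 12 day-1 libraries of hours 16 and 20 nearer the first 4 collections, against a day difference, and 3 of 24 for the day-2 libraries of the same clock times, which was undecided. A later test, on tree by day differences, gave 15562 among 2:00 to 14:00 (46 libraries), 7318 among 10:00 and 14:00 (24 libraries) and 1 among 18:00 and 22:00 (24 libraries), which argues against both; a batch of sampling, extraction or sequencing, for which no label is given, cannot be told apart from a change in the trees themselves (23118).

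A set of 724 transcripts of low level (median 0.723 CPM) rose and fell together, and few of them were called rhythmic. It was found by its correlation above 0.8 with the 247 transcripts of the normalized table, and its mean share of counts went from 0.263% in the first 4 to 0.0381% in the last 8 collections in tree 3A and from 0.0128% to 0.0714% in tree 1A. Low depth alone as the reason is argued against, since 0.414% of the set were rhythmic, against 55.8% to 63.0% of the transcripts in sets matched for level (1000 draws), though the shared movement for which members were chosen adds to the error of that test and may hide a rhythm. Over the other transcripts the tree by block count was 22322, and 13755 with the share of the set as a covariate, which argues against the set as the whole of the step. One outside source of RNA in varying amount is a candidate explanation, since 100% of the 227 members of at least 1 CPM had a slope near 1 on the rest of the set (interquartile range 0.981 to 1.02). The slopes centre near 1 partly by construction, and a programme of the needle itself with equal changes in all members stays open and untested.

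Other groupings of the same libraries were counted with limma on log2 levels, or for families with edgeR on counts summed per tree. They tell whether chance can be excluded. It can for the 24-hour rhythm, for which 1 of 100 orders of the collections, the real one, gave as many transcripts (30611, highest other 26848), and for time of day (30380, highest other 29331). The gap to the highest other was narrow for time of day, and the median of the other orders was 19987 there and 6999 for the rhythm. Changed orders keep the differences between collections, so large counts arise without a daily course. The comparison bears on the rank of the real order, not on the size of its count. For the neighbouring clock times libraries were exchanged within each tree and day, which leaves an effect of a collection common to all trees uncovered; chance within trees alone is excluded, at 1 of 100 each (6:00 against 2:00, 870 and 181; 10:00 against 6:00, 9577 and 4048; 14:00 against 10:00, 13916 and 5936). The same holds for 18:00 against 14:00 (6943 and 1154), 22:00 against 18:00 (7573 and 2190) and 2:00 against 22:00 (7261 and 1124). Chance is excluded too, at 1 of 100 each, for trees (45304 and 2) and the single trees (1A 2674 and 2, 1B 3311 and 46, 2A 2834 and 360, 2B 5560 and 1618, 3A 5722 and 2110, 3B 3425 and 317, all 6 trees 477 and 0). For tree by block, 1 of 100 choices of 4 collections, the real one, gave as many (24769, highest other 4203), but this parting was picked after the data were seen and had the largest count of 9 such partings (23118 without the doubted pair, against 16437 and 15122 for the partings beside it), so this does not exclude chance.

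For the days, the real grouping alone of 32 (1 of 32) gave as many (14990, highest other 14479), a narrow gap. For the daily curve between days, all 32 of 32 groupings gave as many as the real one (3891, highest other 14717). This grouping cannot judge the count, because exchanging the days at some clock times turns the difference between days into one of curves. For the 12-hour term 57 of 100 gave as many (8026, highest other 24916), which cannot judge the count either, because changed orders put the 24-hour rhythm into that term. For rhythms that differ between trees, 3 of 100 gave as many (296, highest other 2972). That share met the bound set for excluding chance, but a first run with fewer draws did not. Exchanging tree labels within a collection also breaks up the differences between trees, which then enter the error or the tested term. This grouping therefore cannot judge the count either. The 15 ways of pairing 6 trees are too few to judge the families by a share (11, highest other 75, 3 of 15 as large).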

How the results depend on the processing

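The pair of libraries left out or exchanged, the first 4 or last 8 collections alone, the linear trend and the tree by block term were chosen after the data were examined; the other alternatives were not.

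The 24-hour rhythm passed 20402 to 32581 transcripts under alternatives that kept the filter, the hours and the ratio, among them each day alone (22347 and 28141), DESeq2 (31981) and the authors' normalized values (26753). It fell to 146 with the collection-time labels as hours, which put samples of different titles at one time. Summing counts over the trees gave 20402, from 12 sums, and a ratio of at least 2 gave 11814. DESeq2 size factors moved no count by 1.5 times.

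Without a filter (173932 transcripts tested) the counts were 58894 for the rhythm, 52478 for time of day, 101817 for trees, 2557 for the daily curve between days and 0 for families. At least 1 CPM in all libraries left 18360 transcripts, fewer to call. It gave 13286 for the rhythm, 13369 for time of day, 9446 for the days, 17390 for trees, 2 for families, 9 for rhythms that differ between trees and 4371 for the 12-hour term. Between neighbouring clock times, from 6:00 against 2:00 onward, it gave 564, 4802, 6562, 4687, 3279 and 4616.

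Without the tree as a replicate block, which leaves tree differences in the error, the counts were 21429 for the rhythm, 19201 for time of day, 7706 for the days, 487 for the daily curve and 2942 for the 12-hour term. The neighbouring clock times, in the same order, gave 211, 4449, 7778, 2609, 3641 and 2979.

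With each tree left out in turn, 6:00 against 2:00 gave 492 to 676, 2:00 against 22:00 gave 4787 to 7021, the daily curve 1589 to 4993, rhythms that differ between trees 239 to 327, the 12-hour term 5451 to 7372 and families 0 to 0. The lowest of these came without tree 2B, or without 3A for rhythms that differ between trees. The cause was not tested.

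With the tree by block term, 6:00 against 2:00 gave 2041, the days 4774 and rhythms that differ between trees 163. In the last 8 collections alone, with fewer libraries, the days gave 6181, 22:00 against 18:00 gave 12659, families 1 and rhythms that differ between trees 70. Single-tree rhythms were then 217 in 1A, 5368 in 1B, 2787 in 2A, 4950 in 2B, 4257 in 3A, 1527 in 3B and 143 in all 6 trees. Without the doubted pair the daily curve gave 6341, families 0 and rhythms that differ between trees 173. With their labels exchanged, families gave 0, rhythms that differ between trees 183 and the rhythm of tree 1B 6727. The cause of these shifts was not tested.

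Families depend on the test. Limma on mean log2 levels per tree gave 87, and limma on libraries with an estimated correlation within trees gave 6646, against 11.

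Of 310 values of named transcripts under alternatives, 266 kept direction and side of the threshold, 41 kept direction alone and 3 reversed, all of psme_t004418. With a tree left out its day change ran from −1.20 (tree 1A) to 7.64 (tree 2A), and over all alternatives from −2.76 in DESeq2 to 9.38 without the replicate block. Its change from 14:00 to 18:00 ran from −0.29 (tree 1A) to 12.9 with a tree left out, and was 14.0 in the last 8 collections. Tree 1A holds both libraries with this transcript at a high level. With 12 libraries per fit, 5% of simulated 2-fold rhythms were recovered in single trees, in a simulation that changed few transcripts.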

Other observations

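The test on the 12-hour term below was set before its result was seen; the values beside it were chosen after the data were examined.

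A 12-hour term may mark a daily curve that is not a cosine rather than 2 peaks a day. If so, transcripts with that term should often pass the 24-hour test too. Of the 8404 transcripts, 80.4% did, against a median of 62.0% (61.1% to 63.0%) in 1000 draws matched for level. The draws were not matched for noise or for change over the day, so this does not tell a single peak of another shape from 2 peaks, and both stay open. Reordered collections could not judge the 12-hour count itself.

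Some transcripts had much of their level at 1 clock time. The 20392 transcripts examined had passed the pooled test on clock times and had a mean of at least 1 CPM. Passing that test on the same libraries favours agreement between trees, so the counts do not describe transcripts in general. Of the 20392, 33 had over 50% of the summed level of the 6 clock times at the same one in all 6 trees. Of these 33, 28 were at 14:00, 4 at 10:00 and 1 at 6:00. The clock time of highest level was the same in all 6 trees for 2047 transcripts, most often 14:00 (732) and 18:00 (478) and least often 2:00 (25).

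Presence and absence also differed between trees. Of 13946 transcripts with a mean of at least 10 CPM in some tree, 169 (1.21%) had at most 0.1 CPM in another. Of these, 75 were that low in 1 tree alone, and 11 in both trees of family 3 alone, against 2 for family 2 and 0 for family 1. In the correlation of tree profiles across transcripts, which are not independent replicates, trees 3A and 3B stood at 0.237, 2A and 2B at −0.19 and 1A and 1B at −0.20, and the other 12 pairs ran from −0.39 to 0.0985. Centring the profiles of 6 trees put the mean over the 15 pairs at −0.199, so 2A and 2B and 1A and 1B stood near that mean.

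The 247 transcripts of the normalized table alone held 0.0209% of its total. Of these, 8 (3.24%) were rhythmic in limma, against 56.3% of transcripts matched for level.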
